A study of Caenorhabditis elegans with 2 samples.

How the data were processed

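ChIP-seq against UNC-62 was measured in 2 biological replicates of whole C. elegans of a transgenic strain, both in 1 group, with the replicate numbers taken from the labels. The authors deposited region lists on builds ce10 and ce11, per the labels and the file lists. Per build there was 1 list per replicate and 1 list called on both replicates together. These hold peaks and background made as input for IDR. A further list was labelled optimal IDR-thresholded and is called reproducible here. Per the deposited file lists the calls used a control, which was not used here. The aligner, the peak caller and their versions are not given in the sources used here. Chromatin was fragmented by sonication, per the labels.

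Each list is in narrowPeak format. The deposited signal value of each region (column 7) is the authors' own enrichment value per region, whose scale is not stated, and it was used only to describe, rank and filter regions within a list. The deposited −log10 q value (column 9) is the authors' as well. Since the pooled and reproducible lists mix both replicates, their signals are the authors' values for the pool, with no SD or n. Total reads are not in the files, so depth is unknown and no value could be set against it.

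Positions were read as 1-based, summits were taken from the summit column, and coordinates were never converted between builds. For ce11, sequence came from the WBcel235 assembly and genes from Ensembl release 115 of the same assembly (46926 genes, 19985 protein-coding), with symbols of mitochondrial protein genes from the RefSeq gene table of that assembly. For ce10 no sequence was used, and chromosome lengths were set to the highest region end in its lists.

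A match between lists was a summit within 200 bp. Chance levels came from 1000 circular shifts of the regions along each chromosome, 1 random offset per chromosome and shift; for the recovery of reproducible regions the reproducible summits were shifted rather than the replicate summits, which leaves the same relative offsets. Promoters were 1000 bp upstream to 200 bp downstream of a transcript start, of protein-coding genes for the promoter share and of all annotated genes for the gene lists. Gene lists were tested with Fisher's exact test against all other annotated genes, adjusted by Benjamini-Hochberg over 28 lists. Motifs were sought within 100 bp of summits and in windows of equal width 1000 bp to either side, with an exact two-sided sign-flip test over regions and adjustment over 10 motifs or over 2080 hexamers; 4 of the 95 regions lay too close to a sequence end and were left out. Chromosome counts were compared with 100000 multinomial draws by length. Confidence intervals are exact binomial at 95%, and tests are two-sided with a threshold of 0.05. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

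The steps were tested on simulated data. Random sets of 95 regions passed the promoter test in 2.50% of 40 sets, and sets with 25 regions placed at promoters in 100.0%. With 150 of 1000 summits shared, 160 matches were found. For 76 regions, 0.025 lists were called per random set over 46926 genes, and 4 planted ribosomal protein promoters were called in 100.0% of sets. TGACAG planted in 20% of windows was called in 80% of 20 sets by the fixed motif test and in 0% by the hexamer test, and in 40% of windows in 100.0% by both.

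The comparisons, the tests, the gene lists, the motifs and the rule for named genes were fixed before the data were examined. Named were the genes at the 25 regions with the highest signal on ce11 (in whose promoter window the summit lies, or that overlap it, or else with the nearest start), up to 4 members of each list by signal, and unc-62 and unc-119. Other names were chosen after their values were seen. Alternative settings covered the matching rule, the number of top regions, the promoter and motif windows, a stricter list, each replicate alone, other backgrounds and controls, and ce10. The text lists that describe the deposited files were read for their origin and hold no measurement.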

Results

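UNC-62 is a Meis-class homeodomain protein of the nematode Caenorhabditis elegans, a cofactor of Hox proteins. Its binding to the genome was measured by chromatin immunoprecipitation and sequencing (ChIP-seq), in which DNA bound by a protein is pulled down with an antibody and sequenced. The samples were whole animals of strain OP600, which carries a transgene with a GFP and FLAG tagged copy of unc-62 and an unc-119 rescue marker. The labels put the antibody target as unc-62. They give the stage as dauer, the arrested larval form, in 1 field and as D4 worms in another, and the stage is left open here. There were 2 biological replicates in 1 group. No second strain, stage or untagged sample was analysed here, so the comparisons are between the replicates and between the enriched regions and the rest of the genome. Sequencing depth is unknown from the files. All p-values below treat regions, windows or genes as the units, not animals, and an interval on a share covers counting error only.

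On build ce11 each replicate list held 30000 regions, which include background by design, with a median width of 316 bp in replicate 1 and 336 bp in replicate 2. The list called on both replicates pooled, which also includes background by design, held 2155 regions. The reproducible list, labelled optimal, passed the authors' irreproducible discovery rate (IDR) threshold and held 95 regions. All of them were among the top 95 pooled regions by the authors' signal value. On ce10 the authors' reproducible list held 105 regions. In both builds 19 of these lay on mitochondrial DNA, which left 76 nuclear regions on ce11 and 86 on ce10. The deposited −log10 q value was 0.820 for every one of the 95 regions, or a q value of 0.151, which was the highest value in the pooled list and was shared by 103 pooled regions. In replicate 1 the list held 201 regions with q below 0.05 on ce11 and 11 on ce10, and in replicate 2 it held 136 on both builds. The reproducible set is thus a ranking with no pooled q value below 0.05. Its name does not mean that each region was found in both replicates, as 17 of 19 mitochondrial regions had no replicate 2 match.

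The regions with the highest signal lay on mitochondrial DNA and, in the nucleus, at unc-62 itself and at the promoter of rpl-3, which encodes a protein of the large ribosomal subunit. Of the 25 regions with the highest signal values, 18 were mitochondrial and 7 nuclear. The first lay at MtDNA 12368 to 12457 (ce11) in the coding sequence of ND5, a subunit of respiratory complex I, with a pooled signal of 1084. The others in this group lay in or beside ND1, ND2, ND3, ND4, ND4L, ND6, COX1, COX2, COX3, CYTB and ATP6, which encode further subunits of the respiratory chain and of ATP synthase. The mitochondrial regions were not alike in the replicates. All 19 had a summit within 200 bp in the replicate 1 list, with a median signal of 130.6, but 2 of 19 did in replicate 2, at signals of 149 and 42.2. Replicate 1 held 24 mitochondrial regions in its whole list and replicate 2 held 2.

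The 7 nuclear regions among the top 25 lay at 6 genes. A pair of overlapping regions at V 4507810 to 4508153 and V 4508025 to 4508368 (signals 82.4 and 61.0) had summits in 5′ UTR sequence of unc-62 transcripts. The region at III 3867435 to 3867778 (signal 80.01) had its summit 247 bp upstream of rpl-3. On X, a region at 14525734 to 14526077 (signal 62.2) had its summit in intergenic sequence 725 bp upstream of nspc-17, and one at 2996917 to 2997260 (signal 54.5) lay in an intron of Y41G9A.17. The region at II 10563416 to 10563759 (signal 55.5) had its summit 181 bp upstream of cdc-48.1, which encodes an AAA ATPase of protein degradation. The region at III 12612609 to 12612952 (signal 53.2) lay in an intron of Y111B2A.12. All 7 ranked within the first 38 regions of replicate 1 and the first 36 of replicate 2.

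The first comparison asked how far each replicate alone ranks the reproducible regions at the top. All 76 nuclear reproducible regions, among them those at unc-62, rpl-3 and cdc-48.1, had a summit within 200 bp in the full list of each replicate, where 9.07 and 9.10 were expected from 1000 circular shifts. Among the top 95 regions of replicate 1, 62 of the 95 reproducible regions were recovered, or 65.3% (95% exact interval 54.8 to 74.7), against 11.2 by chance. Among the top 95 of replicate 2, 50 were recovered, or 52.6% (42.1 to 63.0), against 0.935 by chance. The reproducible list was derived from these same replicates, so recovery above chance was fixed beforehand and the shares only describe how the replicates contribute. The chance level for replicate 1 is high since shifts within the short mitochondrial genome often land on another region. With nuclear regions alone, chosen after the data were seen, 49 and 50 of the 76 were recovered.

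The second comparison set the replicates against each other without the reproducible list. Of the top 95 regions of replicate 1, 27 had a match in the top 95 of replicate 2, or 28.4% (95% exact interval 19.6 to 38.6), where 1.17 were expected (permutation p = 0.002, the smallest possible). Among the top 1000, 128 matched against 5.12 by chance. Signal values agreed weakly. Over 6921 matched summits the Spearman rho was 0.12 and the Pearson r of log10 signal was 0.25, both across regions, which are not independent replicates. Over the 76 nuclear reproducible regions rho was 0.02, but these were selected for a high pooled signal, which by itself can lower rho. Of these 76, 56 ranked within the first 1000 in both replicates, and the median rank was 84 in replicate 1 and 58 in replicate 2. At the extreme, the region in an intron of ppfr-1 (I 9381285 to 9381628), which encodes a regulatory subunit of a protein phosphatase, ranked 38 in the pooled list but 5250 in replicate 1 and 14229 in replicate 2, and was singled out after its values were seen. The sign of rho depended on which matches entered: it was −0.29 over matches of the top 1000 of either list.

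**Figure D1:**
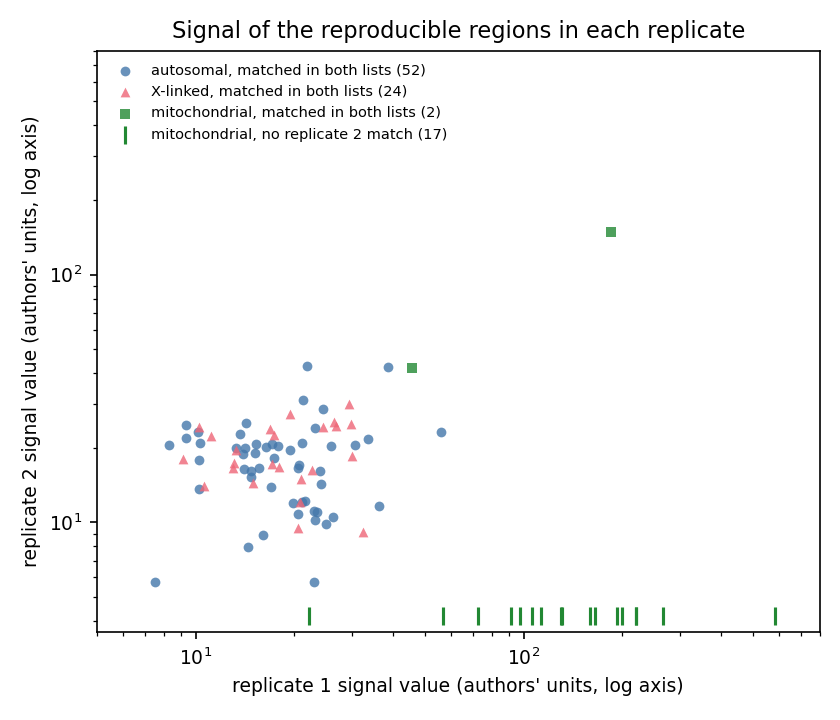
Signal value of each reproducible region in replicate 1 (x axis) and replicate 2 (y axis), in the authors' units on log axes, for the nearest summit within 200 bp. The 52 autosomal and 24 X-linked regions form a cloud with no visible trend, as selection for a high pooled signal can produce, while 17 of the 19 mitochondrial regions, drawn as ticks along the lower edge, had no match in replicate 2.

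The third comparison asked where in gene structure the regions lie. Summits of 50 of the 95 regions, or 52.6% (95% exact interval 42.1 to 63.0), lay between 1000 bp upstream and 200 bp downstream of a protein-coding transcript start, against 33.6 expected from circular shifts (two-sided permutation p = 0.002, the smallest possible). Mitochondrial genes lie end to end, so that 15 of 19 mitochondrial summits fell in such a window against 14.6 by chance. In the nucleus 35 of 76 did, or 46.1% (34.5 to 57.9), against 18.95 by chance (permutation p = 0.002, the smallest possible), including the summits at rpl-3, rpl-20, rpl-15, rpl-35, cdc-48.1 and hsp-60. The 2060 lower pooled regions were all nuclear, and 34.7% of them were at promoters. The like comparison is thus with the 76 (Fisher exact p = 0.0498), as all 95 (Fisher exact p = 0.0006) include the mitochondrial regions. Autosomal regions were at promoters in 29 of 52 cases, or 55.8% (41.3 to 69.5), against 13.7 by chance. X-linked regions were in 6 of 24 cases, or 25% (9.77 to 46.7), against 5.20 by chance, and the difference between X and autosomes had a Fisher exact p of 0.0146. By annotation, 42 nuclear summits were intergenic, 17 in introns, 10 in exons of non-coding genes, 4 in 5′ UTRs, 2 in coding exons and 1 in a 3′ UTR. The nuclear and X splits were made after the data were seen. The excess was not past the threshold in a window of 2000 bp upstream to 500 bp downstream (60%, permutation p = 0.1998) or in the 48 regions with the highest signal (52.1%, permutation p = 0.372). Of these 48, 29 are nuclear, and 10 of the 29 were at promoters against 7.10 by chance (permutation p = 0.304).

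The fourth comparison tested 28 gene lists fixed in advance. Ribosomal protein genes were over-represented: 4 of 78 had a reproducible summit in the promoter window, against 0.191 expected (Fisher exact p = 4.24e-05, Benjamini-Hochberg adjusted p = 0.000396). These were rpl-3 (signal 80.01), rpl-20 (44.6, at IV 4749887 to 4750230), rpl-15 (40.6, at IV 654725 to 655068) and rpl-35 (36.5, at III 7854498 to 7854841), and each was found in both replicates, with replicate 1 signals of 56.1, 20.7, 19.4 and 24.2 and replicate 2 signals of 23.2, 17.1, 19.6 and 14.2. The rpl-20 region also lay in the promoter window of Y17G9B.5, its nearest protein-coding gene, and the rpl-15 region in that of K11H12.8. Genes of small nuclear and nucleolar RNAs were also over-represented, with 8 of 475 against 1.16 expected (Fisher exact test, adjusted p = 0.000334). They comprised 3 genes of SL2 RNA, the leader that is trans-spliced to downstream genes of operons (sls-2.1, sls-2.2 and sls-2.4), and 5 snoRNA genes, of which K11H12.12 and K11H12.13 share the region upstream of rpl-15 and C06A1.9 the one upstream of cdc-48.1. The signal at sls-2.1 (40.2) came with 22.9 in replicate 1 and 5.75 in replicate 2. The list of transgene loci was called through unc-62, 1 of its 2 genes (exact test, adjusted p = 0.0343), and the same gene made up the count of 1 of 6 for the Meis and Pbx class cofactors (adjusted p = 0.0818). Of unc-119, the other transgene locus, neither the reproducible nor the pooled list held a region within 20000 bp.

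For tRNA genes the count was 21 of 634 (Fisher exact test, adjusted p = 1.81e-16), but 19 of these are mitochondrial, among them WBGene00014473, WBGene00014465, WBGene00014452 and WBGene00014453. In the nuclear regions alone 2 remained, against 1.12 expected (exact test, adjusted p = 1.00). The mitochondrial rRNA gene WBGene00014454 made up the count of 1 of 22 rRNA genes (exact test, adjusted p = 0.164). MicroRNA genes had 3 of 260 with a summit (exact test, adjusted p = 0.123), all from mir-54, mir-55 and mir-56 at 1 X-linked region (signal 33.3). The dauer pathway list had 1 of 21 genes, din-1, a corepressor partner of the nuclear receptor DAF-12 (signal 31.3, exact test, adjusted p = 0.164), and the heat shock list 1 of 22, hsp-60, the mitochondrial chaperonin (signal 34.3, adjusted p = 0.164). The region at hsp-60 also lay in the promoter window of Y22D7AL.10, its nearest protein-coding gene. The other 19 lists had 0 genes, with at most 0.659 expected in any of them, so the number of regions is too small to show depletion. They were the Hox, vitellogenin, intestine, hypodermis, muscle, pharynx, neuron, germline, DAF-16 target, heterochronic and Wnt genes and the families of collagens, histones, nuclear receptors, ceh homeobox genes, cytochromes P450, C-type lectins, insulin-like peptides and UDP-glucuronosyltransferases. Of the 28 lists, 4 passed the adjusted threshold and 6 an unadjusted p of 0.05. Against a background of genes with any pooled summit in their promoter, the adjusted p of the exact test was 0.149 for the ribosomal protein list, 0.149 for the small RNA list and 0.385 for the transgene loci, and the small RNA list was also lost in a window of 500 bp upstream to 100 bp downstream (adjusted p = 0.642).

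The unc-62 gene (V 4497461 to 4511449, plus strand) had more pooled regions within 20000 bp than any other nuclear protein-coding gene. The pooled list had 11 regions with summits within 20000 bp of it, 4 before the gene, 6 inside and 1 after. Of these, 3 were reproducible. The pooled list includes background, so those that are not reproducible need not be enriched. The third reproducible region, at V 4499470 to 4499813 (signal 50.8), had its summit 154 bp inside the nearest transcript start. Its signal was 21.8 in replicate 1 and 43.0 in replicate 2, and the region at V 4507810 had 38.6 and 42.2. The 11 summits spanned 22507 bp, from 4489874 to 4512380, and the nearest other pooled summit lay 128161 bp before and 124240 bp after them. The median protein-coding gene had 1 pooled summit within the same distance, and no other of the 19973 nuclear protein-coding genes had 11. These counts were not divided by the length of the window, which is wider for longer genes.

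**Figure D2:**
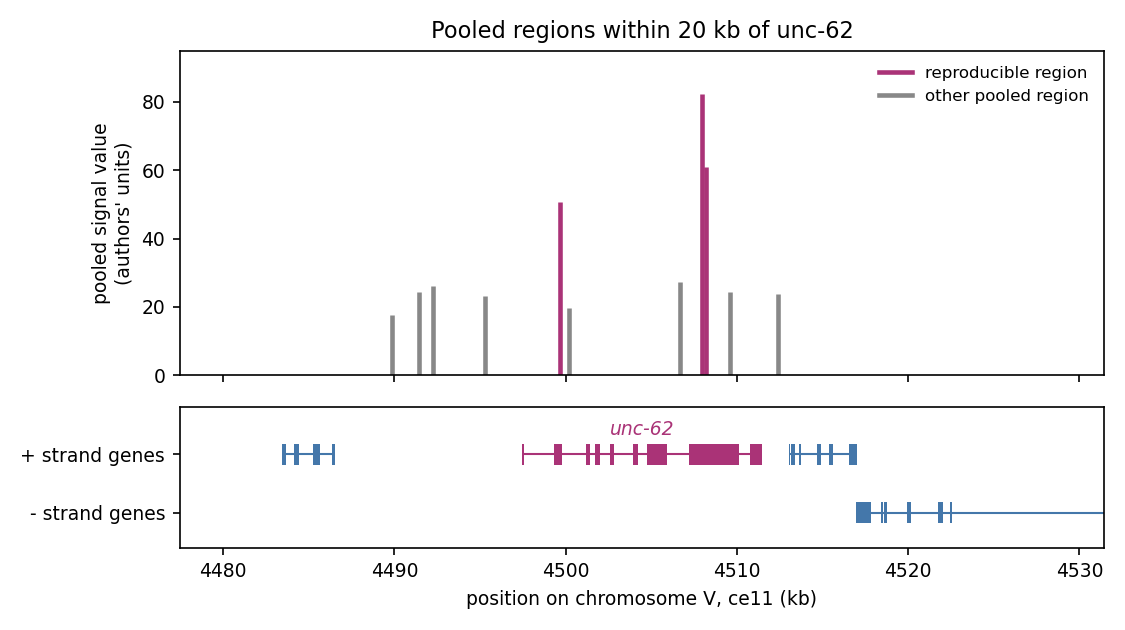
Pooled regions within 20 kb of unc-62 on chromosome V (ce11). Bars in the upper panel stand at the summits and show the authors' pooled signal value, with the 3 reproducible regions in purple and the other 8 pooled regions in grey, and the lower panel shows annotated exons of protein-coding genes by strand.

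The fifth comparison asked which sequences lie under the summits. GAGAGA, a GA repeat unit, was present within 100 bp of 42 of 91 summits with full flanks, or 46.2% (95% exact interval 35.6 to 56.9), and in 12.64% of the 182 windows 1000 bp to either side (exact sign-flip p = 2.03e-07, adjusted p = 2.03e-06 over 10 motifs). All 42 were nuclear, which made 55.3% of the 76 nuclear summits (43.4 to 66.7) against 15.1% of flanks. The motif was at 34 of 52 autosomal summits, or 65.4%, and at 8 of 24 X-linked summits, or 33.3% (Fisher exact p = 0.0130 for the difference, a split made after the data were seen). On X alone the excess over flanks did not pass (exact p = 0.152, adjusted p = 1.00). TGACAG, the core that Meis proteins bind, was at 10 of 91 summits, or 11.0% (5.397 to 19.3), against 3.85% of flanks, a ratio of 2.86 that did not pass (exact p = 0.0655, adjusted p = 0.327). It was at 7.14% of dinucleotide-shuffled copies of the same windows (exact p = 0.396), and within 250 bp at 16.7% of summits against 14.4% of flanks (exact p = 0.680). The composite Pbx and Meis site TGATTGAC was at 0 of 91 summits, which allows a share of up to 3.97% by the exact interval, and at 0 flanks. The GATA site WGATAR was at 28.6% of summits and 37.9% of flanks (exact test, adjusted p = 0.391), and the Pbx and Hox site TGATNNAT at 14.3% and 15.9% (adjusted p = 1.00). CACGTG, TTGTTTAC, TGASTCA, TTGCGCAA and CTGTCTCR were at 6, 0, 1, 2 and 2 summits, and none passed.

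**Figure D3:**
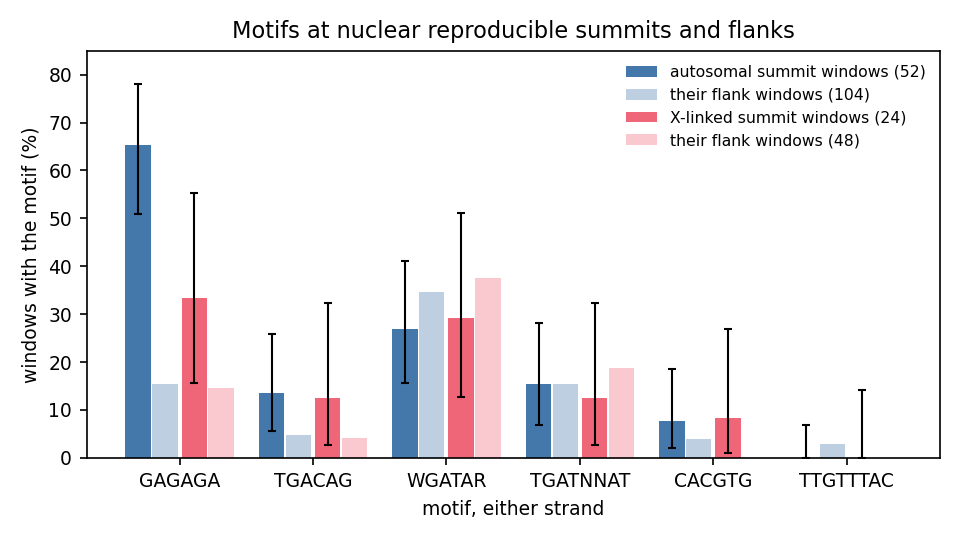
Share of windows with each motif on either strand (y axis, percent) at nuclear reproducible summits on autosomes and on X, with exact 95% intervals, and in windows 1000 bp to either side in lighter shade. GAGAGA stands at 65.4% of autosomal and 33.3% of X-linked summits, with flanks at 15.4% and 14.6%, and the difference on X did not pass (exact p = 0.152).

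Without a preset motif, 43 of 2080 hexamers passed an adjusted p of 0.05, 28 more frequent at summits and 15 less frequent, and 281 had an unadjusted p below 0.05. In nuclear regions alone 31 were more frequent and 36 less. The most frequent among the enriched were GA-rich: GAGAGA, AAGAGA at 42.9% of summits against 13.7% of flanks, AGAGAG at 41.8% against 11.0%, AGAGAA at 36.3% against 17.6%, and AGAGAC at 33.0% against 4.40%. A second kind held CG steps: GCGCGA was at 20.9% of summits and 1.10% of flanks (exact test, adjusted p = 0.00103), and CGCGCA at 17.6% and 1.65% (adjusted p = 0.0287). GCGCGA did not pass in the regions of replicate 1 alone (exact test, adjusted p = 0.359). Among those less frequent were CTGAAA, at 7.69% against 35.2%, and TCAAAA, at 19.8% against 47.3%. In the 48 regions with the highest signal, of which 29 are nuclear, only 1 hexamer passed, and it was less frequent at summits; the adjusted p over all hexamers was 0.417 for GAGAGA (exact test).

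The sixth comparison asked how the regions are spread over chromosomes. Mitochondrial DNA held 19 of 95 regions (20%, exact interval 12.5 to 29.5) against 0.0131 expected by length (permutation p = 2e-05, the smallest that 100000 draws can give). The expectation counts the mitochondrial sequence once, whereas its copies per cell are not known here, so this p does not measure enrichment. Chromosome V held 8 against 19.8 expected (permutation test, adjusted p = 0.00742), among them the 3 at unc-62. X held 24 against 16.8, which was not past the threshold with mitochondrial regions in the total (permutation test, adjusted p = 0.138). Among the 76 nuclear regions, a comparison added after the data were seen, X held 31.6% (21.4 to 43.3) against 17.7% of the sequence, 1.79 times its share (permutation p = 0.00446, adjusted p = 0.0268), and V did not pass (adjusted p = 0.0852). On ce10 X held 25 of 86 nuclear regions, or 29.1% (permutation p = 0.0129, adjusted p = 0.0772), and among the 29 nuclear regions of the top 48 it held 11, or 37.9% (permutation p = 0.0158, adjusted p = 0.0948), so neither passed after adjustment. The regions on X included those near nspc-17, Y41G9A.17, puf-9, which encodes an RNA-binding protein of the Pumilio family, bet-2 and xol-1, the switch gene of sex determination and dosage compensation, 4955 bp from the summit. The last 3 were chosen after their values were seen. In the top 95 nuclear regions of replicate 2 alone X held 32 (permutation test, adjusted p = 0.00168), and in those of replicate 1 alone 26 (adjusted p = 0.154).

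**Figure D4:**
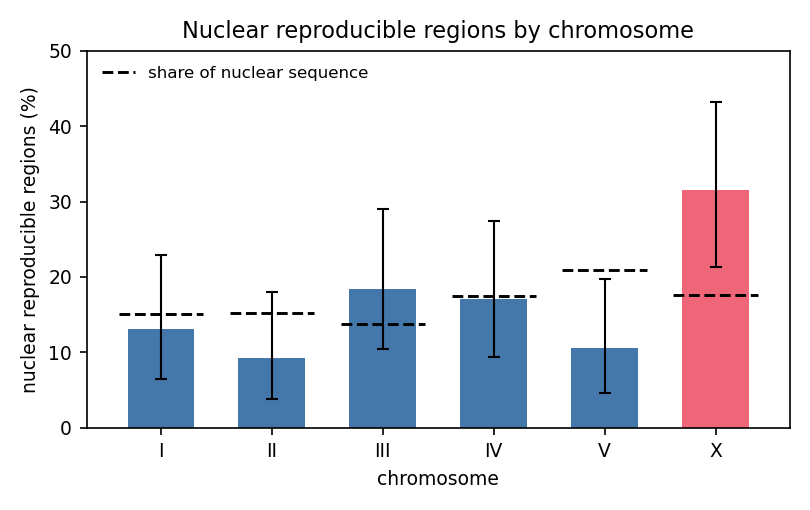
Share of the 76 nuclear reproducible regions on each chromosome (bars, percent, with exact 95% intervals) and the share of nuclear sequence (dashed lines). X stands at 31.6% against 17.7% of the sequence, the other 5 chromosomes between 9.21% and 18.4%.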

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

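The alternatives with nuclear regions only, gene start sites and a background without piRNA genes were chosen after seeing the data. Over 20 results, 123 alternatives were computed. Of 91 with a test, 80 stayed on the same side of the threshold. Direction was compared only for results that passed in the report, and none of these tests reversed. The microRNA list, which did not pass, went from 3 genes to 0 in the top 48 regions and with replicate 2 left out. The 91 include the recovery of reproducible regions, which was fixed beforehand to lie above chance. Of 29 counts, 10 were unchanged and 23 stayed within 1.5 times the count in the report, which does not mean that the same members passed. The share recovered ranged from 61.9% to 77.9% in replicate 1 and from 51.6% to 65.8% in replicate 2, and the overlap of the replicates (11.1% to 33.7%) stayed above chance in every alternative run. GAGAGA was the 1 motif to pass in each of the 7 alternatives, at 32.97% to 56.7% of summits, and TGACAG in none.

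The rank correlation reversed to −0.29 over matches of the top 1000 of either list, where a pair enters because 1 of its values is high, which lowers rho by construction. The promoter share lost its call at 60% (2000 bp upstream to 500 bp downstream) and at 52.1% (top 48 regions), where 10 of 29 nuclear regions were at promoters against 7.10 by chance (permutation p = 0.304), compared with 35 of 76 in the whole list. The causes were not tested. With genes that have a pooled summit as background, 1 gene list was called, the tRNA genes, in place of 4. Hexamers past the threshold numbered 1 in the top 48 regions, 67 in nuclear regions, and 21 to 43 with either replicate left out. The 1 in the top 48 was less frequent at summits, and the 67 were 31 more and 36 less frequent, against 28 and 15 in the report. With replicate 1 left out the split was 20 and 23, with 18 shared with the report, and with low-ranked regions as control 44 and 9. GCGCGA lost its call with replicate 2 left out (exact test, adjusted p = 0.359) and in the top 48 regions (0.387). Chromosomes past the threshold numbered 1 in nuclear regions and 1 to 3 with either replicate left out, where replicate 1 alone called mitochondrial DNA only. The share on X was 31.6% in nuclear regions (permutation test, adjusted p = 0.0268) and 20% to 33.7% with either replicate left out, past the threshold in replicate 2 alone (adjusted p = 0.00126). On ce10 and in the 29 nuclear regions of the top 48 the share on X was 29.1% and 37.9%, where the permutation p was 0.0129 and 0.0158 but the adjusted p was 0.0772 and 0.0948. The microRNA list was called in replicate 2 alone (exact test, adjusted p = 0.00378) and the Meis and Pbx class list in the top 48 regions (adjusted p = 0.0393). For the other settings of these lists the adjusted p ranged from 0.0519 to 1.00. The other causes were not tested.

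Depth is unknown from the files, and the pooled q value of 0.151 limits the reproducible set as a whole. No paired analysis was possible because there is 1 group of 2 samples.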

Other observations

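The tests of the mitochondrial regions, of GA sequence at promoters and of the X-linked sequence, and the genes named next, were chosen after the results were seen, while the tests of the unc-62 locus and of TGACAG were fixed before the data were examined.

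Beyond the genes already named, the 44 nuclear protein-coding genes with a reproducible summit in their promoter window included several of general cell function. lgg-1, an autophagy protein of the ATG8 family, had a region at II 6348423 to 6348766 (signal 36.8, with 17.9 in replicate 1 and 20.3 in replicate 2). A region at IV 6790452 to 6790795 (signal 36.2) lay in the promoter windows of both C17H12.2, the nearest gene, and vha-8, a subunit of the vacuolar proton pump, and a region at X 11605952 to 11606295 (signal 34.2) lay upstream of ftt-2, a 14-3-3 protein. Genes of chromatin regulation were lin-59 (I 3721432 to 3721775, signal 37.8) and set-16 with drr-2 at the same region (III 13643618 to 13643961, signal 38.7). wdr-23, a negative regulator of the stress factor SKN-1, had a region at I 7595469 to 7595812 (signal 32.5, with 10.2 in replicate 1 and 23.1 in replicate 2). The pqn-41 locus on III held 3 reproducible regions in introns (signals 42.3, 39.4 and 33.3). These genes formed no list fixed in advance and were not tested as a group.

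Some X-linked summits carried a sequence found at none of the autosomal reproducible ones. The dosage compensation complex, which in hermaphrodites lowers expression from both X chromosomes, is recruited to X at sites that hold a 12-base motif, here taken as TCGCGCAGGGAG from general knowledge. With at most 2 mismatches it lay within 100 bp of 9 of 24 X-linked summits, or 37.5% (95% exact interval 18.8 to 59.4), of 0 of 48 flanks (exact sign-flip p = 0.00391) and of 0 of 52 autosomal summits (Fisher exact p = 9.18e-06). Of the 3 exact matches on X in ce11, 2 lay within 200 bp of a reproducible summit, at X 2997121 to 2997132 and X 11094123 to 11094134. The best match at the region upstream of nspc-17 was TCGCGCAGGGAC (X 14525898 to 14525909), and that at the region near xol-1 was TCGCGCAGGGAA (X 8036433 to 8036444). Among lower pooled regions the share was 1.73% of 463 on X and 0.689% of 1597 on autosomes. A candidate explanation for the X-linked regions with the motif is that the chromatin pulled down includes recruitment sites of the dosage compensation complex. How much of the X excess they account for was not tested. The hexamers CGCGCA and, read on the other strand, GCGCGA both lie within this motif, so the hexamer result and this one are not independent. Whether UNC-62 itself is there, or whether such sites are recovered with other antibodies too, cannot be read from these lists, and the hypothesis was found and tested on the same regions.

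The regions ranked 1 to 17 by pooled signal were all mitochondrial, and the other 2 ranked 20 and 39. Enrichment called at the same places in both cultures is argued against for 17 of the 19, since 10.5% of the summits had a replicate 2 summit within 200 bp. Reads and the control were not examined, so enrichment too weak to be listed is not covered. The replicate 2 list of 30000 regions, background included, held 2 mitochondrial regions. This count raised the question and is not a separate test of it. An excess of mitochondrial reads over the whole molecule in replicate 1 is possible, but these lists cannot test it. Of the 1000 bp bins of mitochondrial DNA, 92.9% held part of a replicate 1 region, against 14.3% for replicate 2. A bin counted if any base lay in a region. With 24 regions in replicate 1 the share follows in part from their number and does not show even coverage. Regions covered 47.3% of the mitochondrial bases in replicate 1, and the 19 matched signals there were uneven, from 22.1 to 583. The 2 places found in both replicates stay open, as does a difference between the cultures themselves, and no biological explanation was tested, since the design holds 1 group.

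The group of regions at unc-62 has a technical explanation that the data do not exclude. The transgene carries extra copies of the locus, which could raise reads over the whole carried segment. Of the nuclear protein-coding genes, 99.995% had fewer pooled regions within 20000 bp than unc-62 did, by counts not divided by window length. The regions at unc-62 lay on both sides and in the gene body. The 11 summits spanned 22507 bp, and the nearest other pooled summit lay 128161 bp before and 124240 bp after them. A carried segment could give such edges, but its ends are not known here. The signals were uneven, from 17.6 to 82.4, which extra copies neither require nor exclude. At unc-119, the marker on the same transgene, there were 0 regions. That counts against a copy effect only if the marker holds C. elegans unc-119 sequence, which the labels do not say. Binding of UNC-62 to its own gene stays open and was not tested. No input library was used here that would separate these.

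Reproducible regions at promoters may mark open or heavily occupied chromatin rather than sites that UNC-62 recognises. TGACAG was tested over all 91 summits, mitochondrial and non-promoter ones included, and not at promoter summits alone. Its share was 2.86 times that of flanks (exact sign-flip p = 0.0655). It was in 7.14% of shuffled copies against 11.0% of summits (exact sign-flip p = 0.396). Recognition of the Meis core and its absence thus cannot be told apart at these 91 summits, and promoters alone were not tested. GA-rich sequence as a general property of promoters is argued against, since 12.4% of windows at the same offsets from other protein-coding promoters held GAGAGA, against 21 of 35 nuclear promoter summits, or 60% (42.1 to 76.1). The other promoters were not matched for activity or openness, so GA-rich sequence as a property of open or active promoters stays open. What protein or property the GA sequence stands for was not tested. The summits at rpl-3, rpl-20, rpl-15, rpl-35, cdc-48.1 and hsp-60 held neither sequence within 100 bp. No exact TGACAG core thus lay under those summits, and the GAGAGA excess at promoter summits did not extend to them.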
